A study of Mus musculus with 23 samples.

How the data were processed

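Liver RNA from 23 female B6C3F1 mice was hybridised on 2-colour Agilent SurePrint G3 mouse arrays. Per the labels, the sample was labelled with Cy5 and a universal mouse reference RNA with Cy3 on every array, and no dye swap was made. The groups were 5 animals given corn oil, 4 given furan at 1 mg/kg, 5 at 2 mg/kg, 4 at 4 mg/kg and 5 at 8 mg/kg by gavage for 21 days, with tissue taken 4 h after the last dose. The series text counts a slightly larger set of animals in its final data than the 23 arrays that were deposited.

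Per the file headers, the authors scanned each array and extracted it with Agilent Feature Extraction 10.7.3.1, which wrote 62976 spots per array. The deposited scanner files hold 3 kinds of value per spot in each channel. The processed signal is an intensity on a linear scale that the software had background-subtracted and dye-normalised, per the file headers. The median signal and its local background are raw intensities of the spot, per the file headers. The remaining columns are 0 or 1 marks for saturation, non-uniformity, population outliers and signal well above background, per the file headers. The deposited value table holds 1 Cy5 to Cy3 ratio per probe and array on a linear scale, with column medians from 0.974 to 0.987. Its log2 values correlated at 0.995 to 0.997 with a loess of the median signals made without background correction.

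The design fixed before the data were examined called for mean signals with normexp correction. The files hold no mean signals, so the processed signals were used, which the design named as the fallback. It did not say that normexp would be dropped with them, but no further background correction was made on these background-subtracted signals. The values were log2 of processed Cy5 over processed Cy3, then loess within each array (span 0.3, 4 iterations) with control spots and marked spots at weight 0. Control and marked spots were removed and replicate spots of a probe averaged. A probe was kept where its Cy5 signal was well above background on at least 4 arrays of at least 1 group, which left 25574 of 55681 probes. The files give no gene symbol column, so the systematic name of each probe was matched to a gene table of assembly GRCm38.p6, used for names only: 26413 probes matched 20018 symbols. Each gene was represented by its brightest probe and needed at least 3 values per group. The 19898 genes tested included 12926 with a matched symbol and 6972 kept under another name.

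Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 23 arrays, group as the only term, two-sided, Benjamini-Hochberg over all genes tested, threshold an adjusted p of 0.05). A slope on dose, a moderated F test over the 4 doses and a direct comparison of 8 with 4 mg/kg were fitted likewise. The spread rested on 18 residual degrees of freedom, with 2.32 prior degrees of freedom. Simulated groups with 200 genes changed by known amounts were run through the same code. At 8 mg/kg the test recovered 58.2% of 1.5-fold, 76.1% of 2-fold and 97% of 4-fold changes, with 6.1% of calls false; at 4 mg/kg these shares were 55.2%, 82.1% and 95.5%, with 5.49% false.

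The 33 gene lists were fixed before the data were examined: NRF2 and glutathione, p53 targets, integrated stress response and unfolded protein response, heat shock response, immediate early genes, cell cycle and DNA replication, cell death mediators, acute phase response, macrophages and inflammation, Kupffer cells, neutrophils, T and NK cells, B cells and plasma cells, stellate cells and fibrosis, cholangiocytes and progenitors, oncofetal and tumour markers, endothelial cells, erythrocytes, pancreas, adipose tissue, pericentral hepatocytes, periportal hepatocytes, CAR, PXR and AhR targets, PPARA targets, bile acid synthesis and transport, cholesterol synthesis, fatty acid synthesis, gluconeogenesis and fasting, circadian clock, interferon response, sex-biased liver genes, DNA repair, and furan bioactivation and conjugation. Of 783 list entries, 676 were measured, and some genes stand in more than 1 list. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 33 lists within a dose, again with the correlation estimated from the data, and with fry. A list score is the mean, over a list's measured members, of an animal's log2 ratio minus the control mean. Scores of 5 lists (p53, NRF2, heat shock, oncofetal and cell cycle) at 4 doses were compared with controls by two-sided exact permutation tests adjusted over the 20 tests. These tests were not in the fixed design, and all 5 lists passed camera at 8 mg/kg. Their adjusted p values therefore do not cover the choice among 33 lists. Other scores were not tested in this way, among them immediate early genes, which scored 0.20 to 0.56 at 8 mg/kg against -0.16 to 0.10 in controls.

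Genes were named by a rule fixed with the design: the 12 largest rises and 12 largest falls at 8 mg/kg among genes past the threshold with a symbol and with every treated animal on the same side of every control, 5 each way at 4 mg/kg, 3 each way at the other doses and at 8 against 4 mg/kg, the 3 smallest p each way for the trend, up to 4 members per list with the smallest p at 8 mg/kg, and 9 genes given whatever their test (Cyp2e1, Nqo1, Cdkn1a, Mdm2, Ccnd1, Mki67, Gdf15, Hmox1 and Afp). Any gene named outside this rule was chosen after its values were seen, and the text says so. Where every array of a group was dim for a gene, only an approximate lower bound of the fold is given, from the normalised Cy5 signal. That signal combined the loess ratio with the mean intensity of both channels, quantile normalised between arrays. On each dim array the gene was set to its own signal or to the dimmest signal that counted as well above background, whichever was higher. Some signals that counted as dim may lie above that limit, so the bound is not strict.

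Arrays lay on 5 slides scanned on 4 days, of which 2 held 1 array of each of the 5 groups and the others did not, so slide was also fitted as a block and differences were computed within each slide that held both groups. Genes and lists called on these same animals tend to keep their sign within slides through that choice. Where every treated animal lies on 1 side of every control, the sign within slides is fixed. Such agreement in sign is therefore descriptive and not independent evidence. Replicate numbers did not pair the animals. The alternatives tried were no background correction, normexp with offset 10 on median signals, no further loess, median centring, scale normalisation between arrays, Cy5 alone with quantile normalisation, the deposited table, marked spots kept, other dim-probe and probe-per-gene rules, slide, scan day, array position and replicate number as blocks, array weights, a trended robust prior, fits of 2 groups only, a log dose scale, stricter thresholds and leaving out each array. Added after the data were seen were normexp with offset 50 on median signals, array row and array column as separate blocks, a fit without the arrays rich in pancreatic transcripts, and 4 further gene lists. No genome coordinates were used. The number of arrays per group limits the precision of every comparison. Single values of some genes counted in the lists and among the groups tested for outlying animals are not reported here.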

Results

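Liver gene expression was measured in female B6C3F1 mice, a hybrid strain used in carcinogenicity testing, after 21 days of oral furan. Furan is a volatile compound formed when food is heated, and the liver oxidises it, mainly through Cyp2e1, to a reactive dialdehyde. The 23 arrays covered 5 control animals given corn oil, 4 animals at 1 mg/kg, 5 at 2 mg/kg, 4 at 4 mg/kg and 5 at 8 mg/kg. The series concerns cell death and regenerative growth in the exposed liver, so each dose was set against the controls, 8 mg/kg was set against 4 mg/kg, and a trend over dose was fitted. Values are log2 ratios of liver RNA to a common reference RNA, and changes are log2 differences between group means ± standard error.

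Between 22006 and 30120 probes per array were well above background, and 0 Cy5 spots were saturated. Arrays of the same group correlated with a median of 0.976 and arrays of different groups with a median of 0.974. The median residual SD of a gene was 0.236 on the log2 scale. The arrays lay on 5 slides, of which slide 2 held no control, slide 3 no 4 mg/kg animal and slide 5 no 1 mg/kg animal, so within-slide differences come from 4 slides at 2 and 8 mg/kg and from 3 slides at 1 and 4 mg/kg.

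Markers of other tissues set some arrays apart. Pancreatic digestive enzyme transcripts scored 3.46 and 3.30 above the control mean in replicates 1 and 5 at 2 mg/kg, 3.75 in replicate 1 at 4 mg/kg and 2.58 in replicate 5 at 8 mg/kg, against at most 0.41 on any other array. Replicate 4 at 2 mg/kg scored 2.20 on the neutrophil list, against at most 0.62 elsewhere. The hepatocyte lists were higher on slide 3, whose 4 arrays come from 4 different groups: 83 of 91 members of the pericentral, periportal, CAR, PXR and AhR, and bile acid lists were higher there, with a median shift of 0.77.

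**Figure D1:**
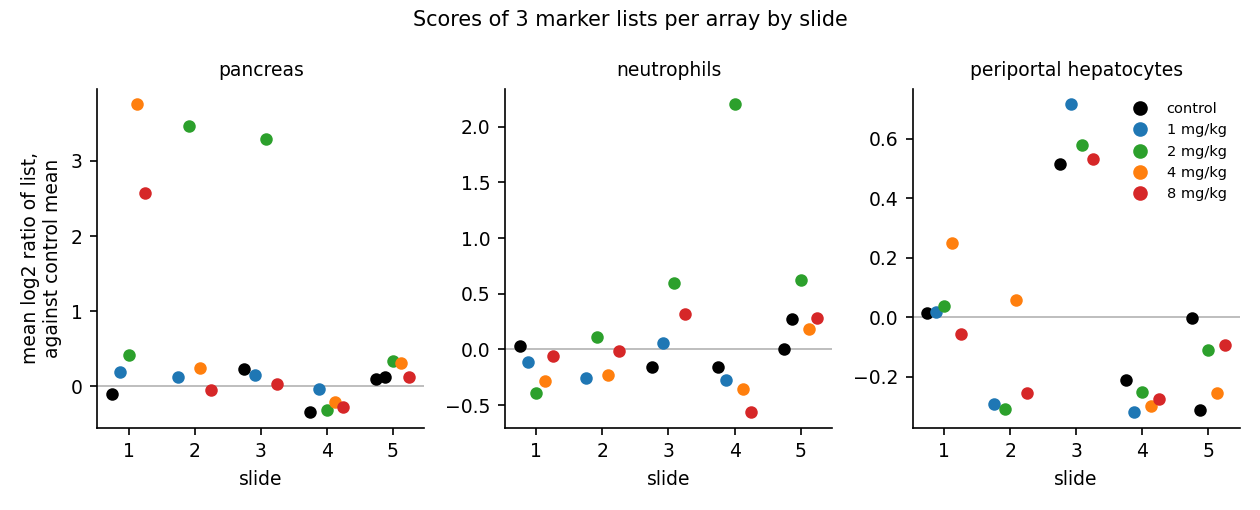
List scores (mean log2 ratio minus the control mean) of the pancreas, neutrophil and periportal hepatocyte lists for each of the 23 animals, by slide, with colours for dose. The pancreas score lies at 2.58 or above on 4 arrays and at 0.41 or below on all others, and the periportal score is higher on slide 3.

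At 8 mg/kg, p53 targets rose together: 16 of 23 measured members rose, 0 fell and 7 did not pass the test. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.79 ± 0.16 (6.9-fold; 5 treated and 5 control animals; limma adjusted p = 1.98e-09). The nuclease gene Aen rose by 1.33 ± 0.09, the death receptor gene Tnfrsf10b by 2.21 ± 0.20, the Akt inhibitor gene Phlda3 by 1.22 ± 0.11, the stress cytokine gene Gdf15 by 2.24 ± 0.23 and Mdm2, which encodes the ubiquitin ligase of p53, by 0.66 ± 0.08. The median change of the list was 0.84, and its animals scored 0.98 ± 0.11 (SD, n = 5), above every control (exact permutation p = 0.00794, the smallest this design allows, adjusted 0.0227). The list passed camera at an adjusted p of 4.65e-25, and of 1.61e-05 with an estimated correlation. Adjusted over the list alone, 17 members were higher and 1 lower, and with slide as a block these counts over all genes were 17 and 1. Within slides the list score was 0.94 to 1.12 higher than control, Cdkn1a 2.59 to 3.34 and Aen 1.04 to 1.55.

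Genes of the NRF2 antioxidant and glutathione group also rose at 8 mg/kg, with 18 of 43 measured members higher, 0 lower and 25 not passing. Gsta1, a glutathione transferase gene, rose by 4.06 ± 0.59 (16.7-fold, n = 5 and 5, limma adjusted p = 2.28e-04). Ephx1, which encodes microsomal epoxide hydrolase, rose by 0.91 ± 0.12, the quinone reductase gene Nqo1 by 1.01 ± 0.16, the thioredoxin reductase gene Txnrd1 by 0.59 ± 0.08, the sulfiredoxin gene Srxn1 by 0.81 ± 0.11 and the heme oxygenase gene Hmox1 by 1.09 ± 0.25. The median change was 0.27 and the animals scored 0.47 ± 0.15, all 5 above every control (exact permutation p = 0.00794, adjusted 0.0227). The camera adjusted p was 5.56e-12, and 0.0173 with an estimated correlation. Adjusted over the list alone, 20 members were higher and 2 lower. The slide-blocked fit gave 18 and 0. Within slides the score was 0.36 to 0.65 higher, Gsta1 2.90 to 6.60 and Nqo1 0.95 to 1.30.

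Heat shock genes, which encode protein-folding chaperones, rose in 10 of 15 measured cases at 8 mg/kg, with 0 falling and 5 not passing. Hsp90aa1 rose by 0.94 ± 0.16, the small chaperone gene Hspb1 by 0.92 ± 0.15, Hspa4l by 0.72 ± 0.13 and the co-chaperone gene Chordc1 by 0.56 ± 0.09. The list score was 0.45 ± 0.08 (SD, n = 5), above every control (exact permutation p = 0.00794, adjusted 0.0227), and 0.43 to 0.55 within slides. Camera gave an adjusted p of 1.87e-10, and 0.0153 with an estimated correlation. Adjusted over the list alone, 11 were higher and 0 lower, and with slide as a block 10 and 0.

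**Figure D2:**
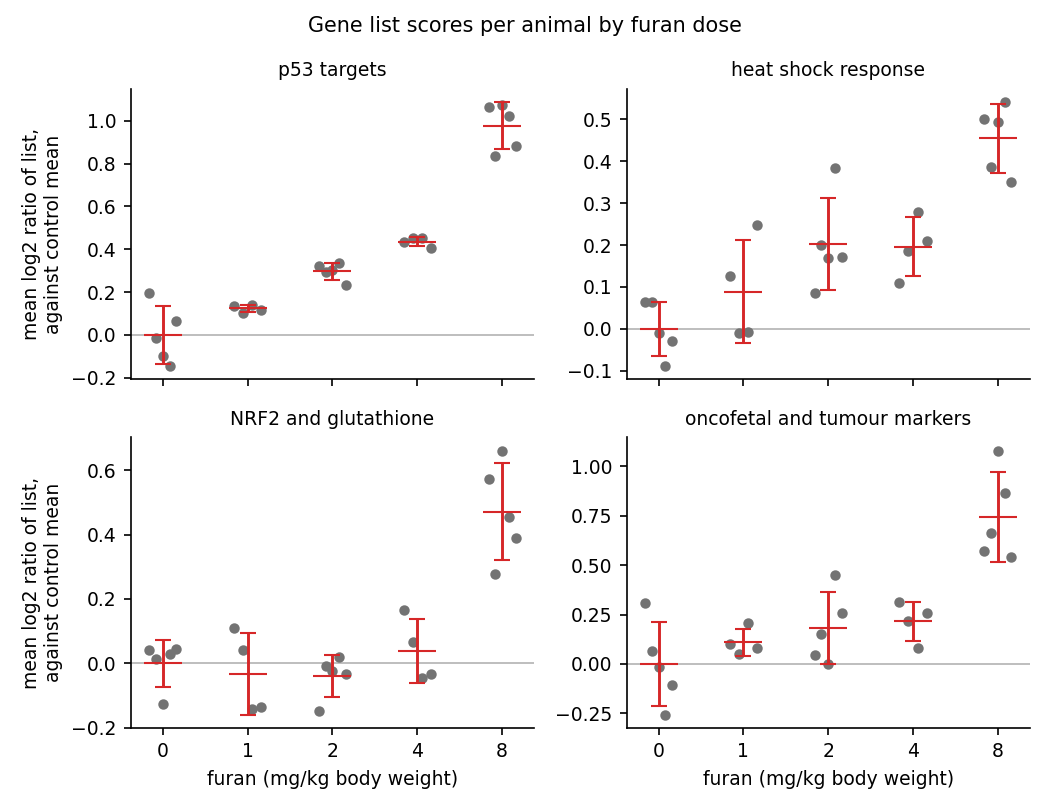
List scores by furan dose (mg/kg body weight) for each animal, with the mean ± SD of each group in red. All 5 animals at 8 mg/kg lie above every control for the p53, NRF2, heat shock and oncofetal lists, and the p53 score is already higher at 2 and 4 mg/kg.

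Transcripts typical of fetal liver and liver tumours rose at 8 mg/kg in 6 of 16 measured cases, with 0 falling and 10 not passing. None of these 10 had an unadjusted p under 0.05 either, so the rise is shown for part of the list only. Afp, the fetal serum protein gene, rose by 2.58 ± 0.28 (5.99-fold, n = 5 and 5, limma adjusted p = 9.43e-06). The tubulin genes Tubb2a and Tubb6 rose by 2.23 ± 0.30 and 0.82 ± 0.12, and the Golgi protein gene Golm1 by 0.80 ± 0.16. The list score was 0.74 ± 0.23 (exact permutation p = 0.00794, adjusted 0.0227), with all 5 animals above every control, and 0.47 to 1.01 within slides. The camera adjusted p was 4.90e-06, and 0.0322 with an estimated correlation; adjusted over the list alone, 6 were higher and 0 lower, as with slide as a block. Within slides Afp was 1.95 to 3.26 higher and Tubb2a 1.70 to 2.97.

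Cell cycle genes moved in both directions at 8 mg/kg: 7 of 38 measured members rose, 2 fell and 29 did not pass. The mitotic genes Ect2 and Kif20a rose by 1.32 ± 0.25 and 1.25 ± 0.27, whereas the nucleotide synthesis gene Tk1 fell by 0.58 ± 0.10. Mki67, the proliferation marker, differed by 0.68 ± 0.25 (limma adjusted p = 0.106), and the cyclin gene Ccnd1 by 0.68 ± 0.27 (limma adjusted p = 0.139), and neither passed, nor with slide as a block (limma adjusted p = 0.0985 and 0.179), although both were higher within 4 of 4 slides (0.36 to 0.88 and 0.37 to 0.74). The list score was 0.42 ± 0.15, with 4 of 5 animals above every control (exact permutation p = 0.0159, adjusted 0.0353). The list passed camera (adjusted p = 1.62e-06) but not with an estimated correlation (adjusted p = 0.464), and adjusted over the list alone 11 were higher and 2 lower. With slide as a block 11 were higher and 2 lower, and the score was 0.22 to 0.74 higher within slides.

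Among 17 immediate early genes, which respond first to growth and stress signals, 4 rose, 0 fell and 13 did not pass. The transcription factor gene Jun rose by 2.24 ± 0.18 (limma adjusted p = 4.41e-07) and the phosphatase gene Dusp6 by 1.49 ± 0.23. Myc and Jund rose by 1.43 ± 0.40 and 0.46 ± 0.12. Myc passed in 17 of 24 other settings and was lost without control replicate 1, 2 or 3 or without 8 mg/kg replicate 1 or 3. Jund passed in 20 of 24 and was lost without control replicate 1 or 8 mg/kg replicate 1 or 2. Camera gave an adjusted p of 0.00778 for the list, lost with an estimated correlation (adjusted p = 0.330), and 5 members were higher adjusted over the list alone. Within slides Jun was 2.02 to 2.60 higher and the list 0.32 to 0.52.

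**Figure D3:**
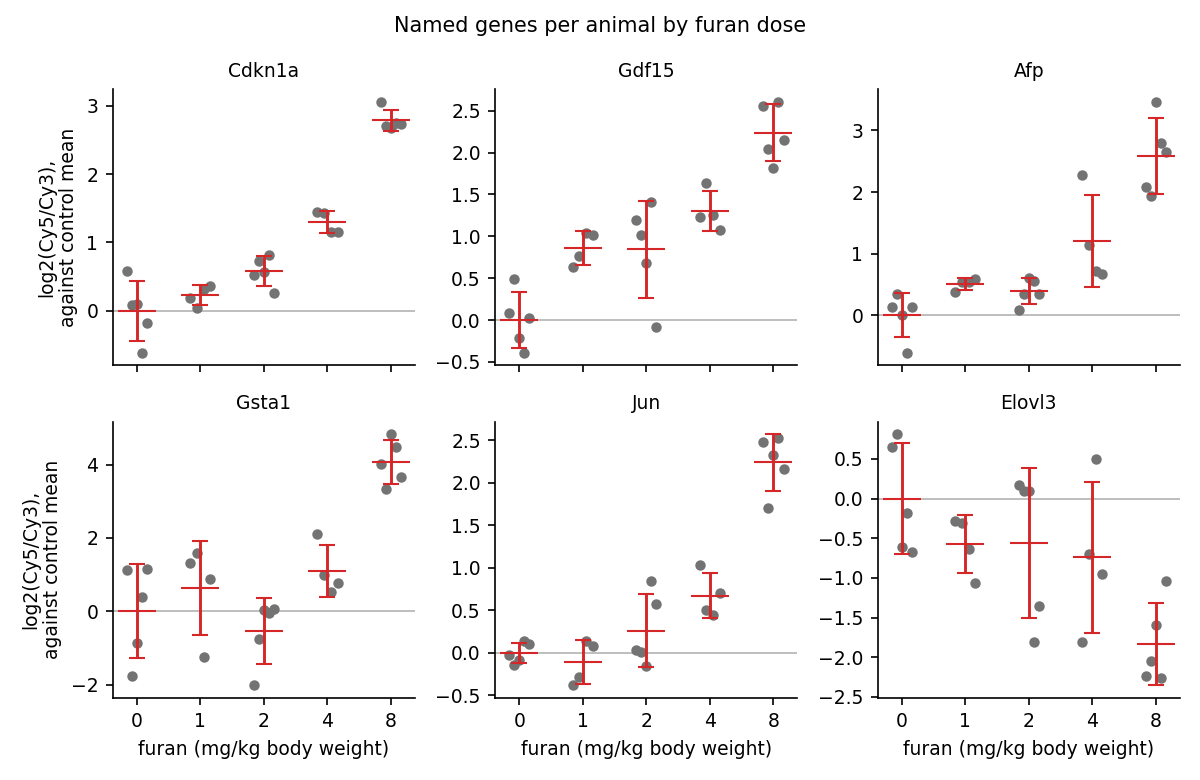
Log2 ratios of Cdkn1a, Gdf15, Afp, Gsta1, Jun and Elovl3 minus the control mean, by furan dose for each animal (grey), with the mean ± SD of each group in red. Before the control mean was subtracted, Cdkn1a rose from -4.12 ± 0.44 in controls to -2.82 ± 0.16 at 4 mg/kg and -1.33 ± 0.16 at 8 mg/kg.

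Stress response and cell death genes moved in both directions at 8 mg/kg, and their lists did not pass camera. In the integrated stress response and unfolded protein response list, 4 of 29 members rose, 2 fell and 23 did not pass (camera adjusted p = 0.0956). Its score was 0.16 ± 0.06 (SD, 0.06 to 0.22), against -0.10 to 0.08 in controls, and was 0.11 to 0.28 higher within 4 of 4 slides. The transcription factor genes Atf3 and Atf4 rose by 1.98 ± 0.19 and 0.60 ± 0.10, Sesn2 by 0.84 ± 0.16 and the hepatokine gene Fgf21 by 2.00 ± 0.44. Chac1, which encodes a glutathione-degrading enzyme, fell by 1.44 ± 0.29, and Trib3, named after its values were seen, fell by 1.09 ± 0.24. Of 31 cell death mediators, 3 rose, 5 fell and 23 did not pass (camera adjusted p = 0.994); fry's test of change in either direction gave an adjusted p of 7.11e-20. The risen genes, all p53 targets too, were Tnfrsf10b, Tnfrsf12a (1.36 ± 0.14) and Bax (0.84 ± 0.11), which encode 2 receptors and a pore-forming death protein. Bmf, which encodes a BH3-only death protein, fell by 1.48 ± 0.27, and Bik, Casp9, Casp6 and Gsdmd, named after their values were seen, fell by 0.37 to 0.93.

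Inflammatory and other non-hepatocyte markers changed little at 8 mg/kg. In the macrophage and inflammation list 2 of 32 genes rose, the chemokine genes Cxcl10 (1.60 ± 0.15) and Ccl4 (1.76 ± 0.38), and the list did not pass (camera adjusted p = 0.227). Ccl4 was well above background on 4 of 5 treated and 1 of 5 control arrays, and it passed in 16 of 23 other settings. Cxcl10 was also the risen gene of 23 interferon response genes, of which the immunoproteasome genes Psmb8 and Psmb9 fell by 0.39 ± 0.10 and 0.37 ± 0.09 (camera adjusted p = 0.490). Of 13 endothelial genes, Eng and Clec14a fell by 0.47 ± 0.14 and 0.48 ± 0.15. The endothelial list passed camera (adjusted p = 0.0161), but not with an estimated correlation (adjusted p = 0.464) nor without control replicate 2. Its 2 falls were lost with slide as a block (limma adjusted p = 0.0712 each), and Eng passed in 8 and Clec14a in 6 of 24 other settings, and in 6 and 8 of the 23 fits that left out 1 array. The list score was nonetheless lower within 4 of 4 slides (-0.45 to -0.20), as were Eng (-1.05 to -0.07) and Clec14a (-0.77 to -0.16). The lipopolysaccharide-binding protein gene Lbp, the 1 fall among 30 acute phase genes, fell by 0.46 ± 0.13 and passed in 12 of 24 other settings and 14 of the 23 fits that left out 1 array (camera adjusted p = 0.994 for the list). No member passed among 10 Kupffer cell, 5 neutrophil, 10 T and NK cell, 5 B and plasma cell, 27 stellate cell and fibrosis, 11 cholangiocyte and progenitor, 5 erythrocyte and 6 pancreas genes, whose lists had camera adjusted p values from 0.446 to 0.994. Of the 79 members of these 8 lists limma called 0, with and without slide as a block, and 2 had an unadjusted p under 0.05. Among 3 adipose genes the lipid droplet gene Cidec rose by 1.33 ± 0.36, lost in 3 of 24 other settings and without control replicate 2, 3 or 4 or 8 mg/kg replicate 3 or 4.

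Metabolic lists moved little. Of 21 fatty acid synthesis genes 3 fell, namely the elongase gene Elovl3 by 1.84 ± 0.44, the acetyl-CoA carboxylase gene Acacb by 0.72 ± 0.19 and the acetyl-CoA synthetase gene Acss2 by 0.50 ± 0.14. This list passed camera (adjusted p = 0.0282) but not with an estimated correlation (adjusted p = 0.997) or with slide as a block (adjusted p = 0.0816) or without control replicate 2 or 5 or 8 mg/kg replicate 2 or 4, and 5 members were lower adjusted over the list alone. Acss2 passed in 11 and Acacb in 18 of 24 other settings, and Elovl3 was well above background on 2 of 5 treated arrays. Of 25 cholesterol synthesis genes Cyp51 rose by 0.65 ± 0.17, with the list at a camera adjusted p of 0.0293 and an adjusted p of 0.997 with an estimated correlation. That list call was lost without control replicate 1, 4 or 5 or 8 mg/kg replicate 1, 3 or 5, and Cyp51 was lost without control replicate 4 or 8 mg/kg replicate 1, 3 or 5. Among 21 genes of furan bioactivation and conjugation, Ephx1 and the glutamate-cysteine ligase gene Gclc (0.75 ± 0.15) rose, and Nat2 and Acy1, which encode an N-acetyltransferase and an aminoacylase, fell by 0.53 ± 0.09 and 0.44 ± 0.12. Cyp2e1 itself differed by -0.34 ± 0.27 (limma adjusted p = 0.536), and with slide as a block by -0.29 (limma adjusted p = 0.00998), with within-slide values from -0.51 to -0.10. The pericentral list had 1 fall in 23 (Oat, -0.46 ± 0.13), and the periportal list 1 in 25 (Pigr, -0.55 ± 0.15), which passed in 11 and 14 of 24 other settings. Of 32 PPARA targets 1 rose (Fgf21) and 2 fell, among them the peroxisomal oxidation gene Acaa1a by 0.42 ± 0.13, which passed in 10 of 24 other settings. The 24 CAR, PXR and AhR targets and the 27 bile acid genes gave 0 limma calls each, with 0 and 1 members at an unadjusted p under 0.05, and 1 call each with slide as a block. Pcx fell by 0.31 ± 0.07 among 19 gluconeogenesis and fasting genes, in which Fgf21 rose. Clock rose by 0.76 ± 0.16 among 18 circadian genes, in which Arntl differed by 1.87 ± 0.58 (limma adjusted p = 0.0507). Elovl3 was the 1 fall among 23 sex-biased genes, and 2 of 26 DNA repair genes rose, among them Mgmt (0.38 ± 0.08). The camera adjusted p was 0.994 for these lists other than fatty acid and cholesterol synthesis. Leaving out 1 array kept the calls of Acss2 in 16, Acacb in 20, Acy1 and Pigr in 18, Oat in 15 and Acaa1a in 14 of 23 fits. Median, mean and test differed in sign in lists that did not pass, namely macrophages, Kupffer cells, neutrophils, adipose tissue, pericentral and periportal hepatocytes, gluconeogenesis, circadian clock, DNA repair and furan bioactivation.

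The largest rises at 8 mg/kg fell partly outside these lists. Dppa5a, a gene of early embryonic cells, was dim on all 5 control arrays and well above background on all 5 treated arrays, at least 4.43-fold higher. The phosphatase gene Dusp8, the steroid dehydrogenase gene Hsd3b4 and Prom2 were likewise dim on every control array, and at least 3.87-fold, 3.53-fold and 1.74-fold higher. Dusp8 was well above background on all 5 treated arrays, and Hsd3b4 and Prom2 on 4 of 5. These bounds are approximate and rest on the normalised Cy5 signal with no dye swap. A dye bias common to all arrays cancels between the groups, and of dye biases only one that varied among arrays could move the bounds. Ddias, which encodes an apoptosis suppressor, rose by 3.02 ± 0.31, the trehalase gene Treh by 3.69 ± 0.75, the oocyte growth factor gene Gdf9 by 2.29 ± 0.29, Dnaaf6b by 2.41 ± 0.59 and the transporter gene Abcc12 by 2.28 ± 0.58. Among controls, Ddias, Dnaaf6b and Abcc12 were well above background on 1 array of 5 and Treh on 2, so the sizes of these 4 rises rest largely on dim control signals. Bbs10, a chaperonin-like gene linked to cilia, fell by 1.56 ± 0.16 (limma adjusted p = 3.34e-06). Ncmap, Fibin, Tlr5 (the flagellin receptor gene), Elac1, Apol7b and Kcnk10 fell by 1.14 to 1.45, Nxpe2 by 1.23 ± 0.36 and Unc79 by 1.12 ± 0.30. Nxpe2 passed in 15 of 24 and Unc79 in 16 of 23 other settings, and in 15 and 19 of the 23 fits that left out 1 array. Abcc12 was lost without control replicate 1 or 5.

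**Figure D4:**
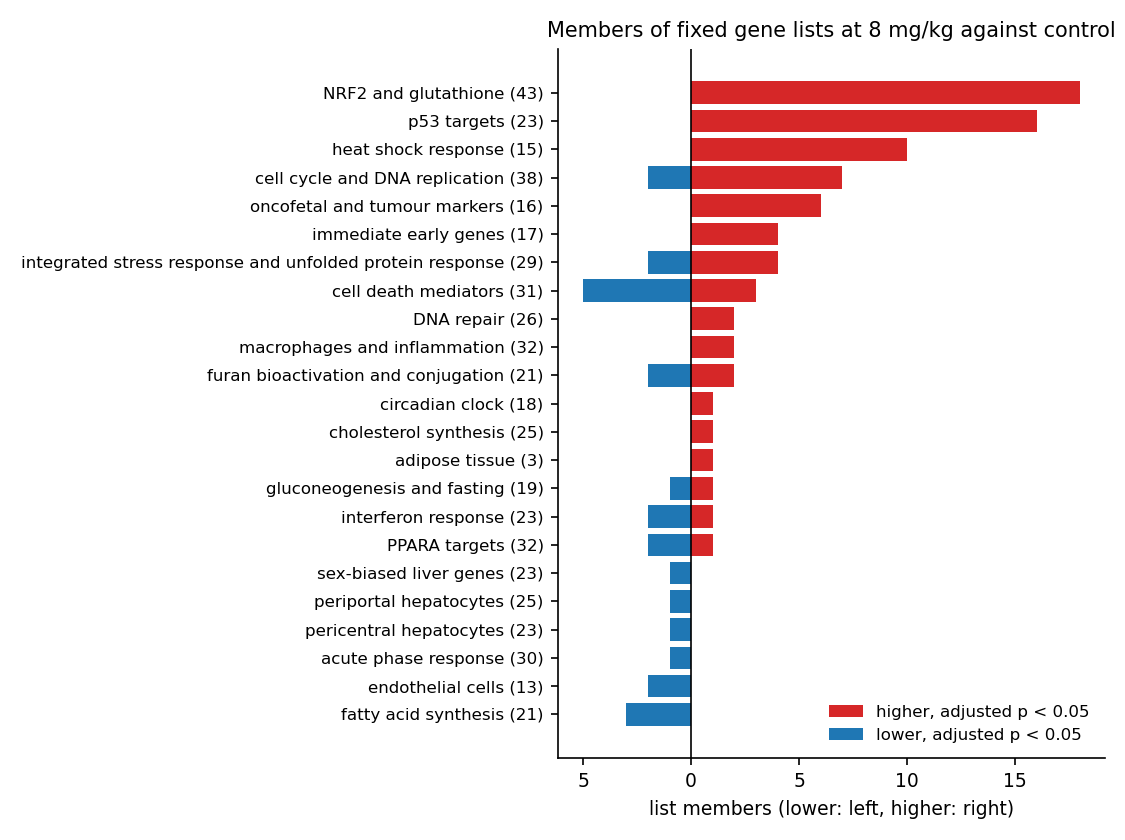
Numbers of list members called at 8 mg/kg against control (limma adjusted p under 0.05), higher to the right and lower to the left. Each fixed list with at least 1 call is shown, with its measured members in brackets. The p53, NRF2, heat shock and oncofetal lists have calls on the higher side only.

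In all, 1593 of 19898 genes changed at 8 mg/kg, 845 higher and 748 lower, of which 529 changed at least 1.5-fold (324 higher, 205 lower). With slide as a block 2326 genes changed, 1550 of them shared, and 1530 of the 1593 had the same sign on all 4 slides that held both groups. The 1593 genes were called on these same animals, which favours that agreement in sign. Every treated animal lay on the same side of every control for 8.75% of genes, against 0.79% by chance. Without the 4 arrays rich in pancreatic transcripts 1240 genes changed. Other settings gave from 69 genes, with array position as a block, to 2454, with slide as a random block. Array position left 11 instead of 18 residual degrees of freedom and standard errors 1.64 times as large. Replicates 1, 2 and 3 at 8 mg/kg shared a position that no other array held, so that fit takes the 8 mg/kg change from replicates 4 and 5. Among the genes named here Dppa5a, Ddias, Cdkn1a, Afp, Jun, Gdf15, Tubb2a, Tnfrsf10b, Atf3, Cxcl10, Tnfrsf12a, Aen, Phlda3, Bax, Apol7b, Elac1, Fibin and Bbs10 still passed with array position as a block.

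At 4 mg/kg, 16 genes changed, 10 higher and 6 lower, and the p53 targets again led. Of 23 p53 targets 3 rose, 0 fell and 20 did not pass: Cdkn1a by 1.29 ± 0.17 (2.45-fold, 4 treated and 5 control animals, limma adjusted p = 0.00137), Gdf15 by 1.30 ± 0.24 (limma adjusted p = 0.0409) and Aen, named after its values were seen, by 0.71. Adjusted over the list alone 10 were higher and 0 lower, with slide as a block 7 and 0. The p53 list score was 0.44 ± 0.02, with 4 of 4 animals above every control (exact permutation p = 0.0159, adjusted 0.0353), and 0.32 to 0.58 within slides. The camera adjusted p was 1.20e-16, and 2.46e-04 with an estimated correlation. Outside the lists, the tubulin gene Tubb4b rose by 0.84 ± 0.13, the mitochondrial import gene Tomm40l by 0.88 ± 0.14 and the carbonic anhydrase gene Car15 by 0.94 ± 0.18. Ahnak, which encodes a giant scaffold protein, fell by 0.98 ± 0.12 and Mettl27 by 0.59 ± 0.10, and Ahnak was lost with the mean over its 4 probes, 1 of which moved the other way. Afp differed by 1.20 ± 0.30 (limma adjusted p = 0.131) and Cyp2e1 by -0.45 ± 0.29 (limma adjusted p = 0.716). Within the 3 slides with both groups Cyp2e1 differed by -0.24 to -0.17. Heat shock genes had 0 members past the test over all genes and 6 higher adjusted over the list alone. Their score was 0.20 ± 0.07 (exact permutation p = 0.00794, adjusted 0.0227), the camera adjusted p was 3.30e-06, and 0.113 with an estimated correlation. Cholesterol synthesis genes passed camera (adjusted p = 9.32e-04) but not with an estimated correlation (adjusted p = 0.933), and 0 members passed.

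The 16 calls at 4 mg/kg had the same sign on all 3 slides with both groups, which their choice on the same animals favours. Slide as a block gave 64 genes, including all 16. Every treated animal lay on one side of every control for 3.62% of genes, against 1.59% by chance, and 1770 genes had an unadjusted p under 0.05. Other settings gave 0 (array position) to 122 genes (slide as a random block), and 5 without the arrays rich in pancreatic transcripts. The count fell to 6 without 4 mg/kg replicate 2 and 8 without 4 mg/kg replicate 3. It was 9 without control replicate 4, 1 mg/kg replicate 3, 2 mg/kg replicate 2 or 8 mg/kg replicate 5. It was 10 without control replicate 2 or 3, 1 mg/kg replicate 2 or 4, or 2 mg/kg replicate 3. Cdkn1a kept its call without any array, Tubb4b was lost without 4 mg/kg replicate 2, Tomm40l without replicate 2 or 3, and Mettl27 without control replicate 2 or 4 mg/kg replicate 2, 3 or 4. Gdf15 kept its call in 8 and Car15 in 5 of the 23 fits that left out 1 array. Of 24 other settings, Gdf15 passed in 16, Mettl27 in 17, Tomm40l in 15 and Car15 in 12.

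At 2 mg/kg, 2 genes passed: Fam13b rose by 0.60 ± 0.10 (1.52-fold, 5 treated and 5 control animals, limma adjusted p = 0.0477), and a transcript with no matched symbol fell. The p53 targets shifted as a group, with a median of 0.27 and a score of 0.30 ± 0.04, all 5 animals above every control (exact permutation p = 0.00794, adjusted 0.0227), and 0.17 to 0.44 within slides. The camera adjusted p was 3.62e-09, and 0.00726 with an estimated correlation; 0 members passed over all genes and 6 were higher adjusted over the list alone. Cdkn1a differed by 0.58 ± 0.16 and Gdf15 by 0.84 ± 0.23 (limma adjusted p = 0.306 each). Heat shock genes scored 0.20 ± 0.11 (exact permutation p = 0.00794, adjusted 0.0227), with 3 higher adjusted over the list alone, a camera adjusted p of 2.77e-05, and 0.163 with an estimated correlation. The integrated stress response list (adjusted p = 8.36e-04), the cholesterol synthesis list (1.79e-08, with 5 members higher adjusted over the list alone) and the acute phase list (0.00107) passed camera. With an estimated correlation their adjusted p values were 0.163, 0.491 and 0.964. The acute phase call was lost without replicate 4, the animal with high neutrophil transcripts, or without replicate 5. Pancreatic genes passed too (camera adjusted p = 0.00809, and 0.850 with an estimated correlation), a call lost without replicate 1 or 5, the 2 arrays of this group rich in these transcripts.

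Fam13b passed in 5 of 24 other settings and had a limma adjusted p of 0.0822 with slide as a block, which gave 0 genes at 2 mg/kg. The limma count without 1 array was 7 without 8 mg/kg replicate 3, 3 without 1 mg/kg replicate 3 or 2 mg/kg replicate 4, 2 without 4 mg/kg replicate 4, 1 without control replicate 4, and 0 without any of the other 18. There were 1723 genes with an unadjusted p under 0.05, and 1.59% of genes had no overlap between the groups, against 0.79% by chance.

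At 1 mg/kg limma called 0 genes, as it did with slide as a block, with 701 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.746. Cdkn1a differed by 0.22 ± 0.17 and Gdf15 by 0.86 ± 0.24, and neither passed. The p53 score was 0.12 ± 0.02 (exact permutation p = 0.143, adjusted 0.260). By camera 4 lists passed: p53 targets and heat shock genes upward (adjusted p = 0.0167 each), 3 adipose genes downward (adjusted p = 0.0167, and 0.0514 with slide as a block) and cholesterol synthesis upward (adjusted p = 1.08e-04). None passed with an estimated correlation (adjusted p = 0.672, 0.904, 0.672 and 0.972), and 0 of their members passed over all genes. Within slides the p53 and heat shock scores were higher on 3 of 3 slides (0.15 to 0.25 and 0.06 to 0.26). Adipose scores were higher on 0 of 3 (-0.34 to -0.05) and cholesterol synthesis scores on 2 of 3 (-0.01 to 0.15). Without 1 mg/kg replicate 4 the p53, heat shock and adipose calls were each lost; the p53 call was also lost without control replicate 2 or 4 or 1 mg/kg replicate 2, the heat shock call without control replicate 4, and the adipose call without control replicate 1 or 5 or 1 mg/kg replicate 2. Genes with no overlap between groups made up 1.33%, against 1.59% by chance.

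Between 8 and 4 mg/kg, the test of the difference itself called 41 genes, 34 higher and 7 lower at 8 mg/kg. Jun was higher by 1.57 ± 0.20 (2.96-fold, 5 against 4 animals, limma adjusted p = 0.001) and Gdf9 by 1.64 ± 0.31. Dppa5a was well above background on all 5 arrays at 8 mg/kg and on 1 of 4 at 4 mg/kg, and its fitted difference of 3.36 ± 0.43 rests largely on dim signals. The p53 targets Cdkn1a (1.49), Tnfrsf12a (1.09), Zmat3 (0.76) and Aen (0.62), and the NRF2 targets Ugdh (0.86), Srxn1 (0.70) and Txnrd1 (0.54), all named after their values were seen, were also higher. Bmf, Bbs10 and the Wnt receptor gene Fzd8 were lower by -1.48 ± 0.29, -0.89 ± 0.16 and -0.73 ± 0.14, in 18, 12 and 8 of 24 other settings and in 16 each of the 23 fits that left out 1 array, against 17 for Gdf9. Within slides Jun was 1.13 to 2.04 higher and Bmf -2.15 to -0.77.

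Slide as a block gave 68 genes for this comparison, 37 of them shared, and other settings gave 0 (array position) to 120 (slide as a random block), with 21 without the arrays rich in pancreatic transcripts. Genes with no overlap made up 4.02%, against 1.59% by chance. The count was 15 without 4 mg/kg replicate 4, 21 without 4 mg/kg replicate 2 or 3, and 20, 27, 26, 22 and 24 without 8 mg/kg replicates 1, 2, 3, 4 and 5.

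Over the dose series, 2068 genes had a slope on dose, 1059 upward and 1009 downward. The slope is a straight line whose shape was not tested, so a change at 8 mg/kg alone can give a call. Single doses gave 0, 2, 16 and 1593 calls at 1, 2, 4 and 8 mg/kg. The number of genes with a graded change is therefore not known. Cdkn1a rose by 0.35 ± 0.02 per mg/kg (limma adjusted p = 3.74e-12), Aen by 0.16 ± 0.01 and Tubb4b by 0.18 ± 0.01. Phyhd1, Cnpy2 and Bbs10 fell by 0.09 ± 0.01, 0.07 ± 0.01 and 0.18 ± 0.02 per mg/kg. Slide as a block gave 3015 genes, 2053 of them shared, and other settings 135 (array position) to 3172 (array weights). A test for any difference among doses called 624 genes, and 1189 with slide as a block. Without 8 mg/kg replicate 1, 2 or 5 that count was 397, 368 or 365, and other settings gave 1 (array position) to 1426 (slide as a random block).

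Doses shared genes in the same direction. Of the 16 genes called at 4 mg/kg, 10 were higher and 4 lower at 8 mg/kg too. Independent lists of these sizes would share 0.425 higher and 0.226 lower, and simulated unchanged groups against the same controls shared 0.1. With the controls split between the doses, the shared calls had a median of 4.5 and a range of 0 to 12. Changes at 8 and 4 mg/kg correlated across genes, which are not independent replicates, at 0.621, against 0.473 for simulated unchanged groups and 0.221 with split controls. The simulated values are means of 20 runs with independent noise for each gene and array. They lack the correlation among genes and among arrays of the same slide (median 0.224), and how far that moves the comparison was not tested. Their covariance was 0.0519 against a simulated 0.025. For 8 and 2 mg/kg the correlation was 0.59 (simulated 0.506, split controls 0.191) and the covariance 0.0455 (simulated 0.0252). For 8 and 1 mg/kg these values were 0.414 (0.472 and 0.057) and 0.0302 (0.0249). The genes called at 8 mg/kg had the same sign at 4 mg/kg in 97.3% of cases, at 2 mg/kg in 94% and at 1 mg/kg in 77.9%; with split controls the shares were 88.7%, 82.1% and 64.5%.

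The Cy3 reference channel, which carries the same RNA on every array, gave 0 of 19898 genes by dose with limma (126 at an unadjusted p under 0.05), 0 at 8 mg/kg, and 2 with slide as a block. Those 126 genes are fewer than unchanged genes would give by chance at that threshold. The count of 0 by dose therefore does not exclude differences in this channel.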

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

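The slide and dose tests of the pancreatic transcripts and the blood test of the neutrophil transcripts were chosen only after the result was seen. Of 533 groups of 4 or 5 animals tested for a value far from the rest, 50 held one, where chance gives about 1 in 20 groups, or 26.6.

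Replicate 1 at 4 mg/kg (pancreas list score 3.75) and replicate 5 at 8 mg/kg (2.58) stood far above their groups, and replicates 1 and 5 at 2 mg/kg scored 3.46 and 3.30. All 8 pancreas genes left out of the main test by the dim filter were also higher on these 4 arrays than on every other array, among them the digestive enzyme genes Cpb1 (by 9.98) and Pnlip (by 8.89), while the amylase gene Amy2a5 did not separate them. The filter needs at least 4 arrays of 1 group, so genes bright on these 4 arrays alone fail it. Failing it thus does not make the 8 genes dim on these arrays. Dim signals on other arrays still leave the sizes of these differences inexact. No whole slide was raised, since the other arrays of the same slides scored 0.41 at most, and 0 dose groups had every animal raised. Both values follow from how the 4 arrays were picked, so they decide neither on a slide or hybridisation effect nor on an effect of furan dose. All 4 arrays came from furan-treated animals, which leaves an effect in some treated animals open. Pancreatic tissue or RNA in the sample remains a candidate explanation, since those 8 genes could have failed to follow the pattern. In the same animal at 8 mg/kg the pancreatic genes Cel, Clps and Ctrl stood at log2 ratios of 4.19, 5.17 and 2.92, far above the other 4 animals.

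Replicate 4 at 2 mg/kg carried 6 of 12 neutrophil genes far above the mean of the other arrays, Mpo by 6.94, Ltf by 6.10, S100a8 by 6.00, Retnlg by 5.87, Ngp by 5.45 and Camp by 4.17, while S100a9, Elane, Mmp8 and Mmp9 differed by 0.59, 0.51, 0.21 and 0.16. Only 5 of the 12 genes passed the dim filter, so some of these sizes rest on dim signals and their order is not exact. Its erythrocyte list score of 0.36 lay above every control (highest 0.25) but below the highest other array (0.62), which leaves blood left in the tissue open. Its macrophage and inflammation score of 0.8 was the highest of all arrays (next 0.4), so inflammation in this animal is a candidate explanation. The receptor genes Csf3r and Cxcr2, which mature neutrophils express, differed from the other arrays by -0.19 and -0.84, and other sources of the raised transcripts were not tested. The same animal had the lowest sex-biased gene score (-1.11, next -0.57) and a high Hmox1 log2 ratio (-0.62) for its group.

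On slide 3 the 91 members of 4 hepatocyte lists had a median log2 ratio 0.77 above the other slides, and its 4 arrays come from 4 groups, so furan dose does not separate them. Chance gives about 1 in 20 groups, and 10 scores of these and related lists from this slide stood far above their group: pericentral genes in control replicate 2 (0.559) and 8 mg/kg replicate 3 (0.578), periportal genes in 8 mg/kg replicate 3 (0.532), CAR, PXR and AhR targets in control replicate 2 (0.53), 1 mg/kg replicate 1 (0.654), 2 mg/kg replicate 5 (0.747) and 8 mg/kg replicate 3 (0.642), and bile acid, furan bioactivation and acute phase genes in control replicate 2 (0.538, 0.266 and 0.511). A lower reference signal on this slide may account for much of the shift, since the Cy3 signal of these genes fell by 0.55 there, 71.8% of the ratio shift. A wider spread of all log ratios on the slide could also take part, as other genes of the same mean ratio shifted by 0.50, 65.1% of the members' shift, but the median absolute deviation of all log ratios was only slightly larger there (1.461, against 1.38 to 1.446 on the other slides). Both remain open, no biological explanation was tested, and with slide as a block the lists concerned gave no camera call at 8 mg/kg.

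Single animals stood apart from their group in other values too. Cyp2e1 reached log2 ratios of 8.06, 8.03 and 7.73 in control replicate 2, 2 mg/kg replicate 5 and 8 mg/kg replicate 3, all on slide 3. Also in 8 mg/kg replicate 3, the macrophage and Kupffer cell scores were 0.302 and 0.578, Cyp2b9, Stard4, Acox2 and Ddias stood high at 11.24, 3.72, 6.75 and 0.85, and Lbp stood low at 2.34. In control replicate 2 Stab1, Glul and A1bg stood high at 4.15, 6.35 and 9.82. In 8 mg/kg replicate 1 the cholangiocyte score was 0.235, Cdkn1a and Plin4 stood high at -1.05 and -0.51, and Psmb9 stood low at 0.25. In 8 mg/kg replicate 5 Sult3a1 stood low at 10.05 and Apol7b high at 1.81. High interferon scores were 0.134 in 2 mg/kg replicate 3 and 0.297 in 4 mg/kg replicate 3, where the DNA repair score was 0.181 and Ahnak stood at -0.25, both high. Low values were a cell cycle score of -0.152 in 1 mg/kg replicate 1, an NRF2 score of -0.128 and Nkg7 at 1.17 in control replicate 3, and Mdm2 at -1.18 in 4 mg/kg replicate 1. In control replicate 4 Ephx1 and Irf7 stood high at 2.42 and 1.21 and Orm3 low at 3.94, in control replicate 5 Por stood high at 2.78, and in control replicate 1 Acaa1a stood low at 3.04 and Des high at 0.84.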

How the results depend on the processing

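Normexp with offset 50 on median signals, array row and array column as separate blocks, and the fit without the arrays rich in pancreatic transcripts were chosen only after the data were seen. The calls of the p53 list at 2, 4 and 8 mg/kg and of the NRF2, heat shock and oncofetal lists at 8 mg/kg were kept under all 26 other settings and without any array, with largest adjusted p values of 0.00726, 2.46e-04, 1.61e-05, 0.0173, 0.0153 and 0.0322. Over other settings, 178 of 283 gene counts stayed within 1.5 times, 78 were smaller and 27 larger; 3237 of 3432 list calls were the same, 74 weaker, 109 stronger and 12 reversed; and 4247 of 4680 calls of named genes were the same, 364 weaker, 69 stronger and 0 reversed. Sign changes of genes that passed under neither setting were not counted. Leaving out 1 array kept 203 of 253 counts, 2972 of 3036 list calls and 4285 of 4508 gene calls, with 0 reversed. The number of arrays and the share of probes well above background (22006 to 30120 of 55681) limit what could be called.

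The counts below stand against 2, 16, 1593 and 41 genes at 2, 4, 8 and 8 against 4 mg/kg, 2068 for the trend and 624 for any dose; where no reason is given, the cause was not tested. Without background correction they were 0 at 2 mg/kg, 1013 at 8 mg/kg and 339 for any dose. With processed signals and no further loess 0 passed at 2 mg/kg. Median centring gave 0 at 2 and 54 at 4 mg/kg. Scale normalisation gave 0 at 2 and 846 at 8 mg/kg, 13 for 8 against 4, 1059 for the trend and 246 for any dose. Cy5 alone gave 0 at 2 and 994 at 8 mg/kg. Normexp with offset 10 gave 0, 1057 and 399 for any dose, and with offset 50 it gave 0, 1009, 1350 for the trend and 333 for any dose. The deposited table gave 0 at 2 mg/kg, 931 at 8 mg/kg, 26 for 8 against 4, 1298 for the trend and 346 for any dose. Without the dim filter, which tests more genes, they were 0, 7, 930, 16 and 321 (any dose). Testing every probe gave 0 at 2 mg/kg. The share of calls that were higher at 8 mg/kg was 53%, and 73.4% with median centring, 63.6% with no further loess, 63.1% without background correction and 69.4% with normexp and offset 50; at 4 mg/kg it was 62.5%, and 88.9% with median centring and 81.0% with scale normalisation. For the trend it was 51.2%, and 73.0% with median centring and 65.3% with normexp and offset 50.

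For the 1593 genes at 8 mg/kg, slide differences as the cause are argued against by 2326 genes with slide as a fixed block. For differences in the reference channel, the Cy3 count by dose was 0% of the log ratio count. Only 126 of 19898 genes had an unadjusted p under 0.05 in Cy3, fewer than unchanged genes would give by chance. That test was therefore too conservative to decide on the reference channel. With slide as a fixed block the count for any dose was 2 in Cy3 and 1189 in the log ratios. The test of array position as the cause was chosen only after the result was seen, and its value was a median ratio of 1. Replicates 1, 2 and 3 at 8 mg/kg all lay at row 1, column 3, where no other array lay. That fit therefore takes the 8 mg/kg change from replicates 4 and 5, for genes called with all 5 animals. Their changes were as large in the median, but position and dose cannot be told apart for replicates 1, 2 and 3, so the test does not decide the question. Slide as a fixed block gave 0, 64 and 68 (8 against 4) genes, 1189 for any dose and 2 in the reference channel. As a random block it gave 7, 122, 2454, 120 and 1426. Scan day as a block gave 1, 69, 67 (8 against 4) and 1195 (any dose). Replicate numbers did not pair the animals: same-numbered arrays correlated with a median of 0.023, with 14 of 43 pairs over 0.1, against 0.224 and 37 of 41 for arrays of the same slide. The replicate block gave 0 genes at 2 mg/kg, 10 at 4 mg/kg and 25 for 8 against 4. Array position as a block gave 0 at 2 and 4 mg/kg, 69 at 8 mg/kg, 0 for 8 against 4, 135 for the trend and 1 for any dose. Its estimates had the same sign for all 1593 genes at 8 mg/kg, with a median ratio of 1 to the fitted changes, and its standard errors were 1.64 times as large on 11 instead of 18 residual degrees of freedom. Array row gave 0, 9 and 25 (8 against 4), and array column 0, 4, 1015, 4 and 215 (any dose). No gene differed by array row or column (0 and 0). Array weights gave 0, 41, 3172 for the trend and 1160 for any dose. Fitting only the 2 groups compared, with fewer arrays for the spread, gave 0, 4, 1039 and 2. Without the arrays rich in pancreatic transcripts the counts were 0, 5, 1240, 21 and 1845 for the trend and 337 for any dose, with fewer arrays. An adjusted p of 0.01 gave 0, 6, 625, 12, 954 and 230, and at least a 1.5-fold change 1 at 2 mg/kg and 529 at 8 mg/kg. With an estimated correlation 4 of 9 lists passed at 8 mg/kg, and fits with split controls shared a median of 4.5 calls between 4 and 8 mg/kg.

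Some lists changed direction. With scale normalisation at 1 mg/kg they were immediate early genes (0.00137), stellate cells (4.58e-04), erythrocytes (0.0222), pericentral (4.62e-08) and periportal hepatocytes (1.33e-07), CAR, PXR and AhR targets (4.06e-05), bile acid genes (8.04e-07) and sex-biased genes (1.12e-06), and at 2 mg/kg periportal hepatocytes (0.0315), all as adjusted p values. With Cy5 alone bile acid genes turned at 2 mg/kg (0.00332) and 8 mg/kg (0.0255), and with array position as a block cholesterol synthesis turned at 1 mg/kg (0.433). Leaving out 1 array gave 0 to 0 genes at 1 mg/kg, 0 to 7 at 2 mg/kg, 6 to 23 at 4 mg/kg, 1155 to 1784 at 8 mg/kg, 15 to 55 for 8 against 4, 1563 to 2398 for the trend, 365 to 727 for any dose and 7 to 9 lists at 8 mg/kg. The counts past 1.5 times are named with their arrays in the results above.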

Other observations

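The 4 gene lists of the first paragraph were written only after the calls at 8 mg/kg were seen, so their direction is not independent evidence. Ribosome biogenesis genes, which build ribosomal subunits in the nucleolus, were higher at 8 mg/kg: 23 of 53 rose and 0 fell, among them Nop58 (0.80 ± 0.11), Rrp12 (0.94 ± 0.17) and Ddx21 (0.68 ± 0.12), with a median change of 0.27 (camera adjusted p = 2.15e-13, and 0.00231 with an estimated correlation). Of 17 tubulin genes 5 rose and 0 fell: Tubb2a, Tubb4b (1.51 ± 0.12), Tuba1c (1.20 ± 0.19), Tuba4a (0.85 ± 0.22) and Tubb6 (camera adjusted p = 1.01e-04, and 0.0264 with an estimated correlation). Lysosomal enzyme genes were lower, with 6 of 46 falling and 2 rising (Gm2a by 0.30 and Gusb by 0.32), and among the falls were the mannosidase gene Man2b1 (-0.59 ± 0.08), the channel gene Mcoln1 (-0.49 ± 0.07) and Naglu (-0.54 ± 0.10), with adjusted p values of 1.14e-04 and 0.0613 with an estimated correlation. Genes of branched-chain amino acid breakdown fell in 4 of 26 cases, Auh (-0.49 ± 0.07), Ivd (-0.40 ± 0.08), Mmut (-0.31 ± 0.06) and Pccb (-0.68 ± 0.18), and 0 rose (adjusted p = 4.86e-04, and 0.151 with an estimated correlation). All 5 treated animals lay beyond every control on each of the 4 lists.

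Other groupings of the same animals tested whether chance could give these results, with 100 groupings per comparison, the real one included. At 8 mg/kg 1 of 100 gave 1593 genes (highest other 3), at 4 mg/kg 1 gave 16 (highest other 5), at 2 mg/kg 1 gave 2 (highest other 1), for 8 against 4 mg/kg 1 gave 41 (highest other 7), for the trend 1 gave 2068 (highest other 1) and for any dose 1 gave 624 (highest other 4). These values argue against chance for the counts other than that at 2 mg/kg. In the other groupings a real change enters the residual spread, which can lower their counts. At 2 mg/kg the margin was only 2 genes against 1, and the count was 0 with slide as a block and in 18 of 23 fits that left out 1 array. Chance is not excluded there. At 1 mg/kg all 100 gave at least the 0 genes of the real grouping (highest other 1).

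The number of lists passing camera is another matter. As many lists as the real 4, 6, 3 and 9 at 1, 2, 4 and 8 mg/kg passed in 70, 72, 75 and 41 of 100 groupings, with up to 18, 21, 20 and 19 lists in another grouping, which correlation among members or a structure of the samples could give. The estimated correlation was 0.033 to 0.72, above camera's preset of 0.01, and with the estimates 0, 1, 1 and 4 lists passed. Arrays of the same slide correlated with a median of 0.224. How far each accounts for the calls in other groupings was not tested. These groupings moved animals across slides, so the spread between slides stayed in them. For single lists, the p53 targets had as small a p in 7, 2, 2 and 1 of 100 groupings at 1, 2, 4 and 8 mg/kg (real p 0.00178, 1.1e-10, 3.63e-18 and 1.41e-26; smallest other 4.66e-06, 9.06e-12, 1.25e-18 and 1.56e-18). Heat shock genes did in 1, 2 and 1 groupings at 2, 4 and 8 mg/kg (2.52e-06, 2e-07 and 1.7e-11; smallest other 8.38e-06, 2.1e-08 and 3.69e-09). At 8 mg/kg NRF2 genes did in 2 (3.37e-13, smallest other 1.34e-13) and oncofetal genes in 2 (7.43e-07, smallest other 1.81e-07). The share of groupings was thus under 0.05 for p53 and heat shock genes from 2 mg/kg on and for NRF2 and oncofetal genes at 8 mg/kg. For each of these lists taken alone this counts against chance, but it does not exclude it. The lists were singled out because camera had called them, and the shares were not adjusted over lists. Heat shock genes did not pass camera with an estimated correlation at 2 and 4 mg/kg (adjusted p = 0.163 and 0.113). These groupings do not count against chance for p53 targets at 1 mg/kg, although their score was 0.15 to 0.25 higher within 3 of 3 slides and the camera adjusted p was 0.00407 with slide as a block. Nor do they at 8 mg/kg for the camera p of cell cycle genes (16 of 100, 1.96e-07; smallest other 3.45e-14), whereas the list score of these genes passed its exact permutation test (p = 0.0159, adjusted 0.0353) and was higher within 4 of 4 slides (camera adjusted p = 6.67e-08 with slide as a block). They do not exclude it at 8 mg/kg for immediate early genes (7, 0.00141; smallest other 1.59e-04) or endothelial cells (9, 0.00342; smallest other 7.93e-05), although within slides their scores differed by 0.32 to 0.52 and by -0.45 to -0.20, each with 1 sign on 4 of 4 slides (camera adjusted p = 0.0235 each with slide as a block). Nor do they exclude it at 8 mg/kg for fatty acid synthesis (17, 0.00683; smallest other 2.31e-04), which lost its camera call with slide as a block (adjusted p = 0.0816). Cholesterol synthesis was as extreme in 45 at 8 mg/kg (0.008, smallest other 1.23e-23) and in 9 at 2 mg/kg (1.08e-09, smallest other 4.66e-17), so chance is not excluded there, with slide as a block at camera adjusted p values of 0.0431 and 2.22e-07. Among other lists called by camera, heat shock and cholesterol synthesis genes at 1 mg/kg had as small a p in 8 and 13 groupings. Integrated stress response, acute phase and pancreas genes at 2 mg/kg did in 6, 37 and 24.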
